A study of Pseudomonas putida with 12 samples.

How the data were processed

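RNA sequencing was done on 12 libraries of Pseudomonas putida EM42, 3 biological replicates in each of 4 groups: glucose (20 mM), glucose with 240 mM formate, a formate dehydrogenase mutant with the same glucose and formate, and glucose with 1 M methanol. Per the labels' protocols, total RNA was enriched with oligo dT, which selects polyadenylated transcripts and is unusual for bacteria, reverse transcribed with random primers and sequenced on a DNB-Seq instrument. The submitters' processing notes name HISAT2, Bowtie2 and RSEM among their tools, without roles. Their versions, the genome build, the annotation, the strand setting and the numbers of reads are not given in the sources used here.

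The deposited files hold an FPKM value per gene (fragments mapped to the gene, relative to its length and to all mapped fragments) made by the authors, 1 file per library, written with a decimal comma. Apart from 2 entries in glucose replicate 1 the files list no entry at 0, and a missing entry was set to 0. An FPKM value is a share of a library, so a few very abundant transcripts lower all others. Libraries were matched by the entry names in the files, in which repeated gene symbols occur and were numbered in file order (as in ccoN.1 and ccoN.2); paralogs that share reads may be divided unevenly between such entries. In all 5352 entries were matched, 5131 were listed in all 12 libraries, and 4 with repeated symbols that could not be matched were left out. A gene symbol is given for 1258 entries (1139 different symbols) and only a locus tag for 4094. The reference table at hand is of another strain of the species: it holds none of the tags and 1088 of the symbols, so tags are left without names and no coordinates are given. Positions of genes relative to each other follow the order of entries, which all files share.

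Depth could be compared only between libraries, and only roughly. The smallest FPKM values of a gene stand for few reads. The commonest log2 ratio of values under 1.5 FPKM to those of glucose replicate 3 lay between -0.23 and 0.03 over 10 libraries. A lower ratio stands for greater depth only where both values stand for equal read numbers, so a ratio near 0 does not show equal depth. No counting intervals can be given without read numbers.

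The file of glucose replicate 1 holds 2 kinds of values, described with the results and weighed at the end. It was left out after the files had been examined and before any test was run, which departs from the design written first (12 libraries). Results with this file as deposited, and with its values restored, were computed as alternatives chosen after seeing the data. To restore them, values were read as days and converted back to hours and minutes. A value of at least 24 with decimals of 60 or more was kept where it lay nearer the other 2 glucose libraries than its conversion did. This use of their levels may understate the spread. Some converted values under 24 had 2 possible readings, and the mean of both was used.

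FPKM values were scaled between the 11 libraries by median-of-ratios factors (0.934 to 1.06) from genes above 0 in every library. Genes with a mean of at least 1 FPKM were kept (5219), and log2(scaled FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend and 1 mean for each of 4 groups, so that the groups share an estimate of the spread. Tests are two-sided and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The comparisons were formate against glucose, methanol against glucose, the mutant against EM42 (both with formate), the mutant with formate against EM42 on glucose, and methanol against formate. Tables and plots were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

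The comparisons, the 27 usable gene lists and the rule for named genes were fixed before the data were examined. The lists were written as KT2440 locus tags and could be used only through their gene symbols, a translation made after the files had been seen and before any test, which leaves out members without a symbol; 2 further lists, the flagellar cluster and the prophages deleted in EM42, could not be used that way. Lists of at least 3 tested genes were tested with camera of limma with a preset correlation between genes of 0.01, adjusted over the lists of a comparison; the same test with a correlation estimated from the residuals is given beside each call. Named genes are, for each comparison, the 8 highest and 8 lowest changes among called genes with a mean of at least 10 in the higher group and no overlap between the groups, up to 4 called members of each list (the member with the largest change where none was called), and the deleted loci. The rule for highest and lowest was restricted to entries with a symbol, plus at most 2 tags per direction, after the files had been seen. Runs are at least 4 neighbouring genes called in the same direction with a median change of at least 1 on the log2 scale, compared with 1000 shuffles of the gene order. Members of the deleted loci without a symbol were taken by their place next to fdnG and fdhF.

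The fitting steps were tested on simulated data in which 200 genes were changed. For formate against glucose, 83 of 100 genes changed by 1 on the log2 scale and 95 of 100 changed by 2 were recovered among 5211 tested, with 8 false calls among 186. For the mutant against EM42 these numbers were 86 and 95 among 5207 tested, with 4 false calls among 185. The noise was drawn independently for each gene, and as many genes rose as fell. Errors of scaling, and spread that genes share, were therefore not tested, and far fewer genes changed than were called against glucose.

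Alternatives were no further scaling, quantile normalization, pseudocounts of 0.1 and 5, no filter and a filter at 10 FPKM, robust limma with weights per library, a fit of only the 2 groups compared, the replicate number as a block, glucose libraries with the same record tag only, and leaving out each library in turn. Other splits of the libraries were fitted for both comparisons of 3 libraries against 3. Tests for count data were not used, since no read counts are at hand.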

Results

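RNA was sequenced from exponential-phase cultures of Pseudomonas putida EM42, a derivative of strain KT2440 from which dispensable regions such as the flagellar cluster and the prophages were deleted. All cultures grew in a minimal medium with 20 mM glucose, and 4 groups of 3 biological replicates were made. EM42 grew on glucose alone, on glucose with 240 mM formate, or on glucose with 1 M methanol. A mutant of EM42 whose genotype names deletions of the formate dehydrogenase loci fdoGHI-fdhE and fmdEFGH (the mutant) grew on glucose with 240 mM formate. Formate and methanol are reduced compounds with a single carbon atom, and the design asks how the transcriptome responds to each of them and whether formate dehydrogenase is needed for the response to formate. The files list 1 FPKM value per gene, for 5213 to 5314 entries per library. The numbers of reads behind them are not given in the sources used here. The commonest log2 ratio of a library's values under 1.5 FPKM to those of glucose replicate 3 lay between -0.23 and 0.03 over 10 libraries. The 3 mutant libraries were at -0.16, -0.23 and -0.23. This ratio is lower in a deeper library only where both values stand for equal read numbers, so it is a rough guide to depth.

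The FPKM values of 11 libraries summed to between 1176095 and 1260196, while those of glucose replicate 1 summed to 554747. Of its 5181 entries that could be compared, 1315 (25.4%) lay at the level of the other glucose libraries, with a median ratio of 1.01, and 3866 lay below it by a median of 23.2-fold. This library was left out of the comparisons, so glucose is represented by 2 libraries and each other group by 3. Means are of FPKM scaled between libraries, followed by ± SD. Changes are differences of log2(scaled FPKM + 1), which understate the change of genes at low levels, with their standard error (SE) and the adjusted p of limma with Benjamini-Hochberg adjustment over 5219 genes.

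In EM42 with formate cydB, a subunit of the cyanide-insensitive bd-type quinol oxidase, rose from 18.5 ± 1.93 (n = 2) to 1189 ± 128 (n = 3), a log2 change of 5.93 ± 0.13 (SE, limma adjusted p = 1.11e-09). All 11 genes of NADH dehydrogenase complex I with a symbol fell (camera adjusted p = 9.76e-14, adjusted p = 0.416 with an estimated correlation), with nuoI going from 813 ± 4.07 to 127 ± 13.0. sucC, of succinyl-CoA synthetase, fell from 7257 ± 329 to 1337 ± 36.7. Among 5219 genes tested, 1120 were higher and 985 lower with formate, and 375 and 208 of these changed by at least 1 on the log2 scale. Which direction holds more calls depends on the scaling: 1319 were higher and 826 lower with FPKM as deposited, and 993 and 1184 with quantile normalization.

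**Figure D1:**
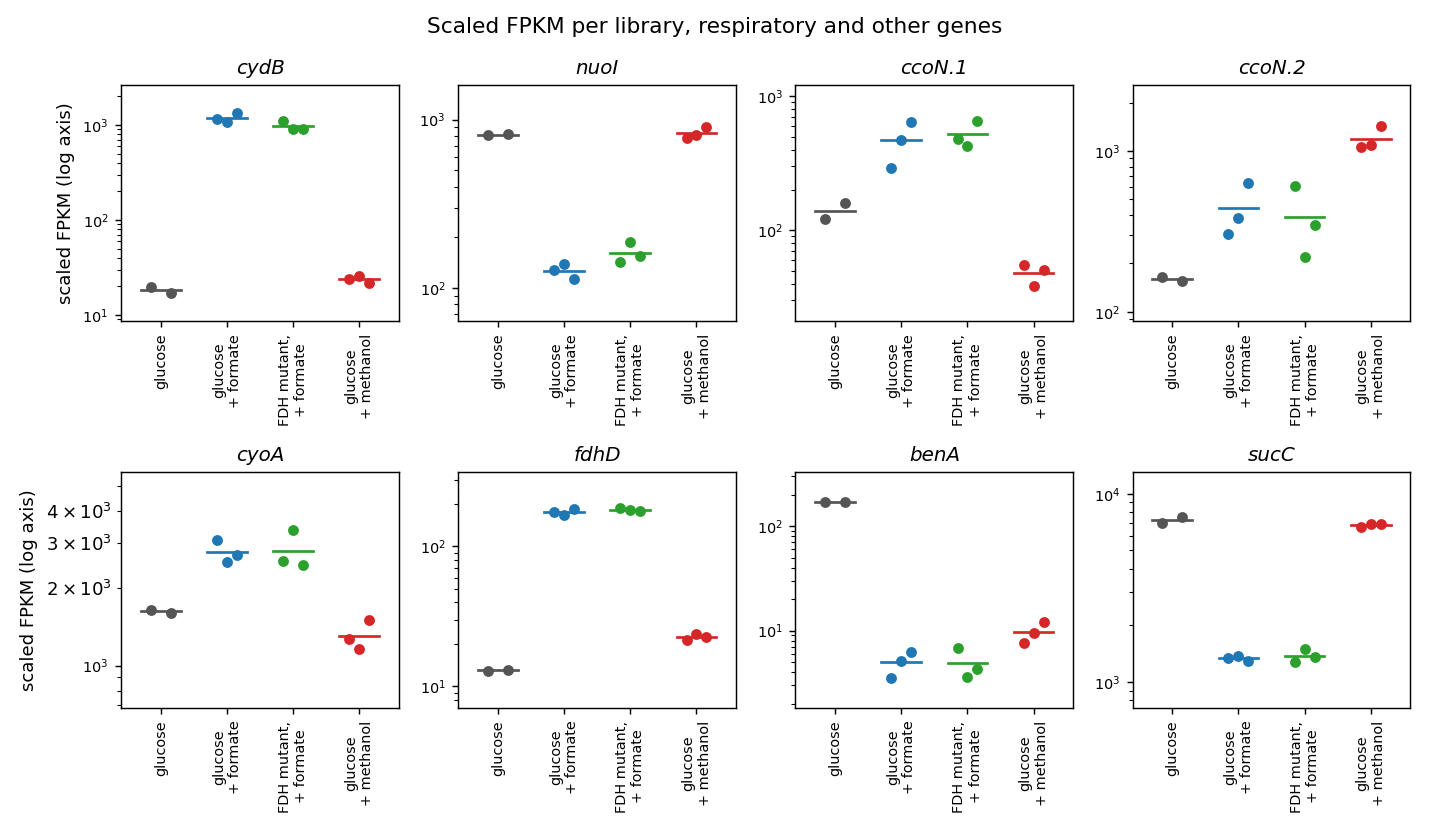
Scaled FPKM of 8 genes in each library, on a log axis, by group; points are libraries and lines are group means. The cydB points of the 6 libraries with formate lie far above those without it, the means being 1189 in EM42 and 965 in the mutant against 18.5 on glucose, while nuoI and sucC lie lower with formate and benA lies lower in all groups but glucose.

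Of 8 measured entries in the formate dehydrogenase loci deleted in the mutant, the 4 with a gene symbol were higher with formate, fdhE from 17.2 ± 1.83 to 38.9 ± 3.65 (log2 change 1.13 ± 0.13, limma adjusted p = 0.000112) and fdnG from 72.5 ± 6.39 to 139 ± 44.7 (0.88 ± 0.25, adjusted p = 0.0176). The other 4, known by tag only, were not called: PP_RS02600 was at 0.06 (limma adjusted p = 0.67), PP_RS11325 at 0.18 (0.637), PP_RS11330 at 0.38 (0.0812) and PP_RS11340 at -0.03 (0.944). The list, which holds only the 4 with a symbol, passed the set test (camera adjusted p = 0.0313), but its adjusted p = 0.416 with an estimated correlation. Without glucose replicate 2 the adjusted p of fdnG, fdxH and fdhF was 0.11, 0.113 and 0.12, without glucose replicate 3 that of fdnG and fdxH was 0.0596 and 0.0626, and without formate replicate 3 that of fdxH was 0.0621. With a pseudocount of 0.1 the limma adjusted p of fdnG, fdxH and fdhF was 0.138, 0.142 and 0.136, so of the 4 with a symbol only fdhE kept its call in that fit. Among 13 other genes linked to formate dehydrogenases, selenocysteine or the molybdenum cofactor, 6 rose, 1 fell and 6 were not called (camera adjusted p = 0.0275, adjusted p = 0.428 with an estimated correlation). fdhD, which is needed for formate dehydrogenase activity, rose from 13.0 ± 0.219 to 176 ± 9.45. moaA, of molybdenum cofactor synthesis, rose from 101 to 510 ± 68.5, and selA and selB, of selenocysteine insertion, rose by 1.14 and 0.94. moaB.2, a molybdenum cofactor gene outside the list, was among the 8 largest rises of entries with a symbol under the rule for named genes (13.7 ± 2.44 to 290 ± 23.3).

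Of 5 cytochrome bo3 genes 4 rose with formate (cyoA by 0.76, cyoB by 0.80 and cyoC by 0.51) and 1 was not called (camera adjusted p = 0.0227, adjusted p = 0.503 with an estimated correlation). Of 6 cbb3-type oxidase genes 5 rose and 1 was not called, ccoN.1 going from 140 ± 26.5 to 470 ± 179 (camera adjusted p = 0.0288, adjusted p = 0.512 with an estimated correlation). The count of 5 depends on single libraries: the limma adjusted p of ccoN.2, ccoO.1 and ccoO.2 was 0.0754, 0.11 and 0.149 without glucose replicate 2. That of ccoN.2 and ccoO.2 was 0.0912 and 0.17 without glucose replicate 3 and 0.0532 and 0.139 without formate replicate 3. ccoO.2 was not called either without formate replicate 2 (limma adjusted p = 0.0789), with quantile normalization (0.0569) or without the filter on low values (0.0512). Of the 2 aa3-type genes measured 1 was not called and the other, coxB, was lower by -0.62 ± 0.20 (limma adjusted p = 0.0319). The limma adjusted p of coxB was 0.0992 and 0.152 without glucose replicates 2 and 3, 0.0697, 0.0541 and 0.0735 without formate replicates 1, 2 and 3, and 0.066 with FPKM as deposited. None of the 5 ATP synthase genes was called (camera adjusted p = 0.84). The complex I list had the smallest camera p of all lists, with nuoJ at -2.67, nuoN at -2.51 and nuoL at -2.51. In the tricarboxylic acid cycle and glyoxylate shunt, 5 of 12 genes fell, 2 rose and 5 were not called (camera adjusted p = 0.0222, adjusted p = 0.416 with an estimated correlation). sucD changed by -2.29 and odhB, of 2-oxoglutarate dehydrogenase, by -1.84. aceA, isocitrate lyase of the glyoxylate shunt, rose by 2.92 ± 0.92 (limma adjusted p = 0.0285) but its levels in the 3 formate libraries were 182, 338 and 1412, and its adjusted p was 0.0777 without formate replicate 3, 0.116 without glucose replicate 2 and 0.111 without glucose replicate 3.

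Genes of PQQ-dependent alcohol oxidation and of the synthesis of the cofactor PQQ also rose with formate, 6 of 9 being higher and 3 not called (camera adjusted p = 0.0133, adjusted p = 0.503 with an estimated correlation). pedF, the cytochrome c of this oxidation system, went from 4.37 ± 1.35 to 332 ± 347 (log2 change 5.41 ± 1.05, limma adjusted p = 0.00244) and pqqC from 104 ± 4.54 to 461 ± 240. Without glucose replicate 2 the limma adjusted p of pedH and pqqD.2 was 0.0806 and 0.066, and that of pedH was 0.0917 without glucose replicate 3 and 0.0551 without formate replicate 3. These genes varied strongly between the libraries with formate: pedF stood at 84.3, 183 and 729 in replicates 1, 2 and 3. exaA, a PQQ-dependent alcohol dehydrogenase, stood at 220, 572 and 2785 against 79.0 and 133 on glucose, and was not called. The share of all FPKM taken by ribosomal protein genes was 17.4%, 15.7% and 14.4% in the same libraries, against 19.1% and 20.1% on glucose. Of 53 ribosomal protein genes 17 fell, 36 were not called and none rose (camera adjusted p = 1.36e-05, adjusted p = 0.612 with an estimated correlation), with rpsU at -1.17 and rpmF at -0.90.

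Chaperones and proteases of the heat shock response rose in 10 of 12 genes, with 2 not called (camera adjusted p = 2.83e-05, adjusted p = 0.416 with an estimated correlation). hslV, a subunit of the HslUV protease, went from 188 ± 13.9 to 752 ± 66.8, clpB rose by 1.87, lon.1 by 1.68 and grpE by 1.41. Type VI secretion genes rose in 12 of 28 cases, fell in 2 and were not called in 14 (camera adjusted p = 0.0122, adjusted p = 0.416 with an estimated correlation), from low levels such as 1.33 ± 0.192 to 14.7 ± 1.66 for tssC.1. Of 3 genes for methionine and S-adenosylmethionine synthesis 2 fell and 1 was not called (camera adjusted p = 0.04, adjusted p = 0.416 with an estimated correlation). ahcY, which recycles S-adenosylhomocysteine, changed by -2.21. The other, metK, was at -0.20 and not called with quantile normalization (limma adjusted p = 0.163). Of 12 genes for folate-bound one-carbon and glycine metabolism 3 rose, 3 fell and 6 were not called (camera adjusted p = 0.677): gcvH.1 and gcvP.1 of the glycine cleavage system rose by 1.49 and 1.13, while metF, methylenetetrahydrofolate reductase, changed by -2.12. The third higher gene, gcvP.2, had a limma adjusted p of 0.112 and 0.215 without glucose replicates 2 and 3, and 0.0951 and 0.139 without formate replicates 2 and 3. It was not called either with quantile normalization (0.0528), without the filter on low values (0.0517) or with glucose replicates 1 (restored) and 2 as controls (0.0619).

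The remaining lists did not pass the set test with formate. Of 4 oxidative stress genes the catalase-peroxidase gene katG rose by 1.85 and ahpF by 0.89, katE changed by -0.78 and 1 was not called (camera adjusted p = 0.695). Of 13 osmotic and envelope stress genes 5 rose and 8 were not called (camera adjusted p = 0.0588), with osmE at 1.69, treS.2 at 1.08 and betA, of betaine synthesis, at 0.83. The iron list had 3 of 5 genes higher and 2 not called (camera adjusted p = 0.416), bfr.1 (bacterioferritin) rising by 1.94. The limma adjusted p of bfr.2 was 0.16 and 0.145 without glucose replicates 2 and 3, 0.0669, 0.104 and 0.0862 without formate replicates 1, 2 and 3, and 0.0932 with glucose replicates 1 (restored) and 2 as controls. That of fur was 0.236 without glucose replicate 2, 0.092 without formate replicate 2 and 0.058 with quantile normalization. The polyhydroxyalkanoate list had 2 of 3 higher and 1 not called (phaC.1 1.30, phaZ 1.13; camera adjusted p = 0.0588). The efflux list had 2 of 3 higher and 1 not called (ttgB 0.63; camera adjusted p = 0.218), and the limma adjusted p of ttgA was 0.0782 without glucose replicate 3. Among 11 purine synthesis genes 3 fell, 1 rose and 7 were not called (camera adjusted p = 0.11), purD being at -0.87. Among 14 sulfur genes 3 fell, 1 rose and 10 were not called (camera adjusted p = 0.584), with cysK at 1.13 and cysM at -0.52. Among 6 genes of the Entner-Doudoroff pathway and nearby steps 2 rose, 1 fell and 3 were not called (camera adjusted p = 0.696), pgl being at 0.52. None of the 4 betaine demethylation genes (camera adjusted p = 0.922), the 6 exopolysaccharide genes (camera adjusted p = 0.695), the 2 formaldehyde oxidation genes or the 1 glucose uptake gene measured (ugpC, log2 change -0.67, limma adjusted p = 0.166) was called. Adjusted over the list alone, the counts were 7 higher for PQQ, 5 for cytochrome bo3, 6 for cbb3, 12 for heat shock and 3 for polyhydroxyalkanoates and 16 lower for ribosomal proteins, and those of the other lists were as given. Among the list genes followed through other fits, at most 4 per list, cyoD, edd, hexR.1, purT, rplI and rpmG also lost their call in at least 1 fit with another scaling, pseudocount, filter or set of libraries.

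Other large changes with formate lay outside the lists. benA and benB, of benzoate oxidation, changed by -4.86 and -4.76, and catA.1, of catechol cleavage, by -2.53. bamA.2 changed by -2.95 and dapF.1 by -2.65, while greB rose by 3.04 and ngg by 3.47. Most called entries carry only a locus tag, which the files do not pair with names. PP_RS24220, a neighbour of cydB, rose from 10.3 ± 2.00 to 902 ± 95.2, and PP_RS16495 fell from 85.8 ± 8.40 to 2.10 ± 0.807. The comparison called 2105 genes; with the glucose replicate 1 file as deposited in the fit it called 1318.

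With methanol, exaA went from 106 ± 37.8 (n = 2) to 14930 ± 2610 (n = 3), a log2 change of 7.16 ± 1.24 (SE, limma adjusted p = 0.00191), and pedF from 4.37 ± 1.35 to 3740 ± 299 (9.46 ± 1.05, limma adjusted p = 0.000125). metK, of S-adenosylmethionine synthesis, fell from 4220 ± 169 to 787 ± 45.1. Among the genes tested, 887 were higher and 687 lower with methanol, 227 and 166 of them by at least 1 on the log2 scale. The excess of higher calls turned with FPKM as deposited (782 higher, 801 lower) and with quantile normalization (728 and 788). The question here is the response to another reduced one-carbon compound, at a higher concentration than that of formate.

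**Figure D2:**
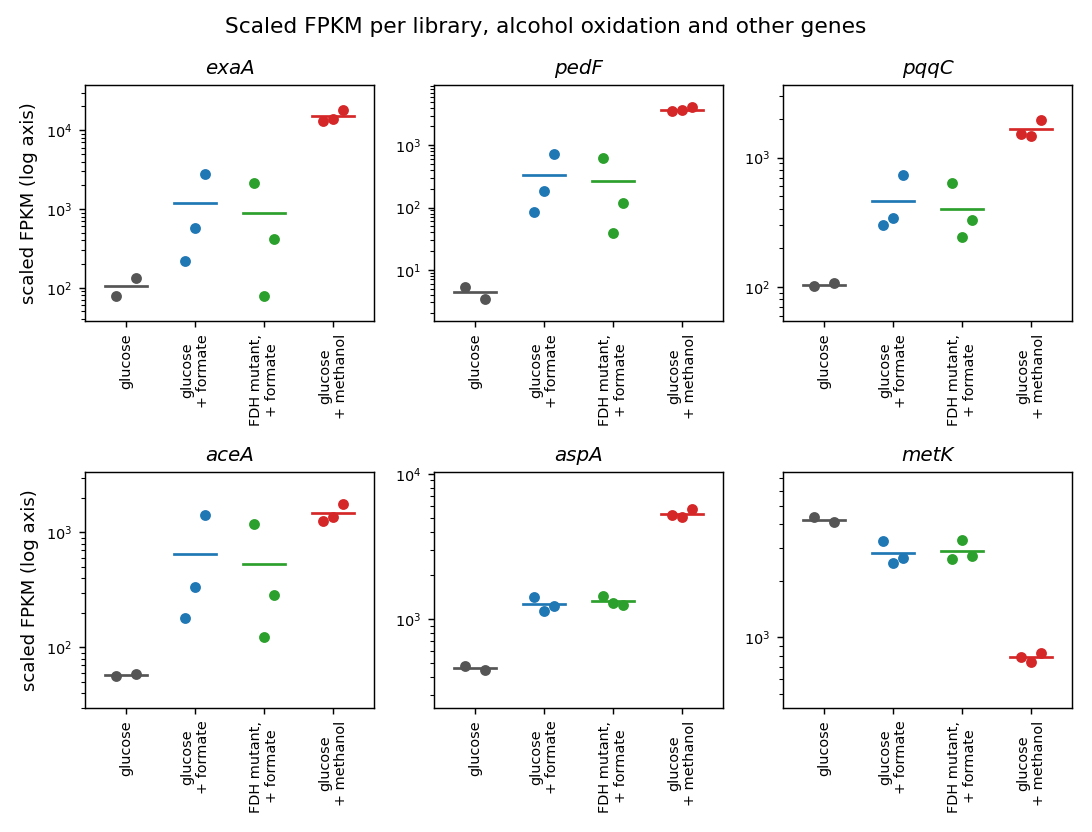
Scaled FPKM of 6 genes in each library, on a log axis, by group; points are libraries and lines are group means. exaA, pedF, pqqC, aceA and aspA have their highest means with methanol, the mean of exaA being 14930, the formate libraries of both strains spread over a wide range for the first 4 of these, and metK is lowest with methanol.

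Of 9 genes for PQQ-dependent alcohol oxidation and PQQ synthesis 8 rose with methanol and 1 was not called (camera adjusted p = 1.12e-05, adjusted p = 0.571 with an estimated correlation). pedH, another PQQ-dependent alcohol dehydrogenase, went from 4.54 ± 0.443 to 728 ± 89.5, pqqC from 104 ± 4.54 to 1654 ± 268 and pqqE rose by 3.37. PP_RS13955, in the same stretch of the file as exaA, went from 7.72 ± 0.578 to 7692 ± 1100. Formaldehyde oxidation had 1 of 2 genes called, fghA (S-formylglutathione hydrolase) at 0.48 with a limma adjusted p of 0.00961, which was 0.0737 without glucose replicate 2 and 0.0526 without glucose replicate 3. fdnG and fdxH of the formate dehydrogenase list changed by -1.29 and -1.19, and its other 2 genes were not called (camera adjusted p = 0.384). Of the 4 tag-only entries of these loci PP_RS02600 was lower (-0.43, limma adjusted p = 0.0132) and the other 3 were not called. Of the 13 other formate dehydrogenase, selenocysteine and molybdenum cofactor genes 3 rose and 10 were not called (moaA 0.88, fdhD 0.75; camera adjusted p = 0.264).

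All 3 measured genes of methionine and S-adenosylmethionine synthesis were lower with methanol (metK -2.42, ahcY -2.25; camera adjusted p = 0.00149, adjusted p = 0.553 with an estimated correlation). The third, metH, had a limma adjusted p of 0.16 and 0.178 without glucose replicates 2 and 3, and 0.127 and 0.123 without methanol replicates 1 and 2. Of 12 folate and glycine genes 4 fell, 1 rose and 7 were not called (camera adjusted p = 0.148), with metF at -2.20, gcvT.1 at -1.91 and gcvP.1 at -1.17. Among the respiratory genes the 2 copies of the cbb3-type oxidase separated: ccoN.2, ccoO.2 and ccoP.2 rose by 2.87, 2.90 and 2.61, and the other 3 genes fell (camera adjusted p = 0.797), with ccoN.1 at -1.52, whose limma adjusted p was 0.0521 without glucose replicate 3. Of 5 cytochrome bo3 genes 2 fell and 3 were not called (camera adjusted p = 0.0851), none of the 11 complex I genes was called (camera adjusted p = 0.881), and cydB was not called (log2 change 0.35, limma adjusted p = 0.06). Neither of the 2 aa3-type genes nor any of the 5 ATP synthase genes was called (camera adjusted p = 0.744 for the latter). Of 12 tricarboxylic acid cycle and glyoxylate genes 2 rose and 10 were not called (camera adjusted p = 0.511), aceA going from 57.8 ± 1.57 to 1464 ± 273.

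Heat shock genes rose in 10 of 12 cases with methanol and 2 were not called (camera adjusted p = 0.000498, adjusted p = 0.705 with an estimated correlation), with grpE at 1.24, lon.1 at 1.24 and hslV at 0.97. Of 53 ribosomal protein genes 10 fell and 43 were not called (camera adjusted p = 2.34e-05, adjusted p = 0.763 with an estimated correlation), with rplU at -0.92 and rpsB at -0.87. The ribosomal share of FPKM was 15.4%, 15.6% and 15.5% with methanol. Of the lists that did not pass the set test, the oxidative stress list had 2 of 4 genes higher (ahpF 1.03, ahpC 0.89; camera adjusted p = 0.148) and the polyhydroxyalkanoate list 3 of 3 (phaZ 1.28, phaC.1 1.07; camera adjusted p = 0.0617). The third of these, phaC.2, lost its call without any 1 library (limma adjusted p = 0.13, 0.16, 0.0748, 0.0822 and 0.0646 without glucose replicates 2 and 3 and methanol replicates 1 to 3). It also did so with FPKM as deposited (0.0588) and with glucose replicates 1 (restored) and 2 as controls (0.105). The efflux list had 2 of 3 higher, ttgB and the repressor gene ttgR (1.00; camera adjusted p = 0.148). The limma adjusted p of ttgB was 0.138 with quantile normalization, 0.0528 with glucose replicates 1 (restored) and 2 as controls, 0.12 and 0.16 without glucose replicates 2 and 3, and 0.092 without methanol replicate 3. Of the osmotic genes 2 rose, 1 fell and 10 were not called (osmE 2.28; camera adjusted p = 0.797), and of the purine genes 3 rose, 1 fell and 7 were not called (camera adjusted p = 0.264). Of 14 sulfur genes 1 rose, 2 fell and 11 were not called (cysK 0.81; camera adjusted p = 0.264), and of 4 betaine demethylation genes 2 rose and 2 were not called (camera adjusted p = 0.148). Of the iron genes 1 fell (camera adjusted p = 0.797), of the type VI secretion genes 3 rose and 25 were not called (camera adjusted p = 0.797), of the Entner-Doudoroff genes 1 rose and 1 fell (camera adjusted p = 0.797), and of the exopolysaccharide genes 1 fell (camera adjusted p = 0.376). Adjusted over the list alone, 5 folate and glycine genes, 5 ribosomal genes and 0 exopolysaccharide genes were lower and 4 purine genes, 1 type VI secretion gene and cydB were higher, with the other counts as given. For cydB, the only tested gene of its list, this is the unadjusted p. Among the list genes followed, acnB, bcsA, bfr.2, choX.2, cyoD, cyoE.2, dgcA, gbcB, gcvH.1, glgB, hexR.1, purF, purL, rpsI, ssuE, tauA, tssB.2, tssC.1, tssG.1 and zwf.1 also lost their call in at least 1 fit with another scaling, pseudocount, filter or set of libraries.

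Outside the lists, aspA, aspartate ammonia-lyase, rose with methanol from 458 ± 19.2 to 5302 ± 343. dapF.1 changed by -4.66, benA by -4.01, benB by -3.75, solA by -3.11 and ptsP.1 by -2.55. PP_RS19675, in the same stretch of the file as dapF.1 and solA, fell from 4234 ± 3.12 to 6.81 ± 0.371. The comparison called 1574 genes. It called 849 with the glucose replicate 1 file as deposited, 856 without glucose replicate 2 and 871 without glucose replicate 3.

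In the mutant, the genes of both formate dehydrogenase loci were absent or nearly so. The files name their members fdnG, fdxH and fdhE in the former locus and fdhF in the latter, with 4 further entries by tag only. fdnG stood at 0.0493, 0.328 and 0.0390 in the 3 mutant libraries and at 93.8, 141 and 183 in EM42 with formate. fdxH was listed for mutant replicate 1 alone, at 0.158, against 31.7, 35.2 and 43.1, and fdhF for mutant replicate 2 alone, at 0.103, against 18, 19.9 and 21.6. fdhE was listed for none of the 3 mutant libraries and stood at 34.8, 39.9 and 41.9 in EM42 with formate; entries that are not listed were set to 0. Over the 8 entries of the 2 loci the highest level in a mutant library was 0.328 and the lowest in EM42 with formate was 5.49.

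**Figure D3:**
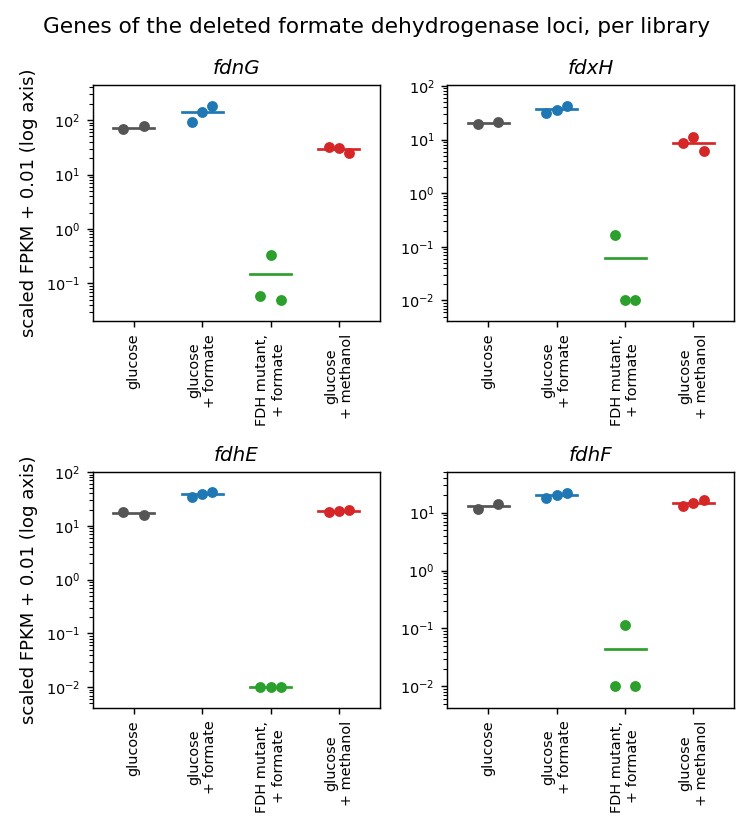
Scaled FPKM + 0.01 of fdnG, fdxH, fdhE and fdhF in each library, on a log axis, by group; points are libraries and lines are group means. All 3 mutant libraries lie at or below 0.328, below every EM42 library.

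This comparison asks which genes depend on formate dehydrogenase when formate is present. In all 43 genes were called, 2 higher and 41 lower in the mutant. Of these, 8 lie in the deleted loci and the other 35 carry only locus tags, 33 of them lower. The largest fall outside the loci was -1.34 on the log2 scale. A higher entry lies at the end of the complex I run (89.9 ± 0.225 to 141 ± 4.98, log2 change 0.65 ± 0.08, limma adjusted p = 0.00309, n = 3 each), and the other rose by 0.41 (limma adjusted p = 0.0431). The limma adjusted p of the latter was 0.128 and 0.169 without mutant replicates 1 and 3, 0.148, 0.116 and 0.142 without formate replicates 1, 2 and 3, 0.0965 with FPKM as deposited and 0.133 with only the 2 groups fitted. selA was at 0.99 ± 0.20 and not called (limma adjusted p = 0.0535), though its adjusted p was 0.00645 without mutant replicate 2. Not called either were cydB (-0.30, limma adjusted p = 0.42), nuoI (0.34, limma adjusted p = 0.311), grpE (0.25, limma adjusted p = 0.777) and exaA (-0.77, limma adjusted p = 0.955).

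Among the lists, the 4 genes with a symbol in the deleted loci passed the set test with either correlation (4 lower, camera adjusted p = 1.1e-27, adjusted p = 0.00151 with an estimated correlation). These genes are deleted in the mutant, so this outcome was fixed in advance. Purine synthesis (camera adjusted p = 0.00409), complex I (camera adjusted p = 0.00743), sulfur assimilation (camera adjusted p = 0.0345) and ribosomal proteins (camera adjusted p = 0.0373) leaned higher in the mutant, with no member with a symbol called and an adjusted p = 0.916 with an estimated correlation for each. Their median log2 changes were 0.10, 0.10, 0.10 and 0.08. The complex I list leaves out the called higher entry of the complex I run, which has no symbol. The share of FPKM in ribosomal protein genes was 13.8%, 19.8% and 15.9% in the mutant libraries. No other list passed, and no member of another list was called. Adjusted over the list alone, 1 cofactor gene was higher and cydB was lower. The list of cydB holds no other tested gene, so its p is then unadjusted. The count of 43 was 26 without mutant replicate 3, 28 without formate replicate 1, and 14 with the glucose replicate 1 file as deposited in the shared fit. It was 166 (37 higher and 129 lower) with robust limma and a weight per library, so the number of genes outside the 2 loci depends on the fit.

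Set against EM42 on glucose alone, the mutant with formate differed in 1052 genes that were higher and 995 that were lower, and genotype and formate change together in this comparison. With quantile normalization the balance turned, to 963 higher and 1135 lower. cydB was higher by 5.63, fdhD by 3.71, moaB.2 by 4.18, greB by 3.05, selA by 2.13 and hslV by 2.03. benA was lower (-4.88), as were bamA.2 (-3.34), nuoJ (-2.58) and sucD (-2.40). The same 11 lists passed the set test as in EM42 with formate. Among them, the list of deleted genes passed in opposite directions. Its median log2 change was 0.84 in EM42 with formate and -4.27 here, where the fall is the deletion itself. Complex I had 11 of 11 genes lower (camera adjusted p = 1.92e-13, adjusted p = 0.222 with an estimated correlation) and the heat shock list 10 of 12 higher (camera adjusted p = 6.72e-06, adjusted p = 0.376 with an estimated correlation). Ribosomal proteins had 10 of 53 lower (camera adjusted p = 0.000251, adjusted p = 0.726 with an estimated correlation), type VI secretion 12 of 28 higher and 1 lower (camera adjusted p = 0.00135, adjusted p = 0.217 with an estimated correlation), and the tricarboxylic acid cycle list 6 of 12 lower and 2 higher (camera adjusted p = 0.0128, adjusted p = 0.351 with an estimated correlation). The other 6 were the genes with a symbol in the deleted loci (4 lower, camera adjusted p = 6.72e-06, adjusted p = 0.177 with an estimated correlation), the other formate dehydrogenase and cofactor genes (5 higher, 1 lower; camera adjusted p = 0.015, adjusted p = 0.376 with an estimated correlation), PQQ (6 higher; camera adjusted p = 0.0163, adjusted p = 0.448 with an estimated correlation), cytochrome bo3 (4 higher; camera adjusted p = 0.0244, adjusted p = 0.448 with an estimated correlation), cbb3 (4 higher; camera adjusted p = 0.0258, adjusted p = 0.448 with an estimated correlation) and methionine (2 lower; camera adjusted p = 0.0354, adjusted p = 0.376 with an estimated correlation). Adjusted over the list alone, the PQQ, cbb3, heat shock and type VI secretion lists had 7, 5, 12 and 13 genes higher, the ribosomal list had 3 lower and ugpC was lower. For ugpC, the only tested gene of its list, this is the unadjusted p. In this comparison aceA, atpB, ccoN.2, ccoO.1, ccoP.1, cyoC, cyoD, edd, folD.2, fur, hexR.1, metK, pedH, pqqD.2, purB, rplS, rpsF, ssuE, tauD and tssB.1 lost their call in at least 1 fit with another scaling, pseudocount, filter or set of libraries. The levels of exaA in the mutant libraries were 2147, 79.1 and 411. With the glucose replicate 1 file as deposited the count of 2047 was 1267.

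Methanol and formate were compared directly, which tests the difference between the 2 responses with the glucose libraries left out of the contrast. The bd-type oxidase gene cydB was lower with methanol by -5.58 ± 0.11 (SE, limma adjusted p = 2.45e-10), at 23.8 ± 2.04 against 1189 ± 128 (n = 3 each), and nuoI of complex I (2.71) and sucC of succinyl-CoA synthetase (2.35) were higher. exaA (4.39), pedF (4.05) and pqqD.2 (3.54) were higher with methanol as well. In all 1283 genes were higher and 1266 lower with methanol. With the FPKM used as deposited, without scaling between libraries, 1029 were higher and 1573 lower, the median of all genes then being -0.11; the changes given here are relative to that shift.

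Complex I was higher in 11 of 11 genes with methanol (camera adjusted p = 1.68e-11, adjusted p = 0.315 with an estimated correlation), with nuoJ at 2.59 and nuoL at 2.50. The tricarboxylic acid cycle list was higher in 8 of 12 genes and lower in 1 (sucD 2.08, odhB 1.86, acnA -1.67; camera adjusted p = 0.00581, adjusted p = 0.315 with an estimated correlation). Cytochrome bo3 was lower in 5 of 5 (cyoA -1.09; camera adjusted p = 0.00581, adjusted p = 0.644 with an estimated correlation). The PQQ list was higher in 8 of 9 (camera adjusted p = 0.0117, adjusted p = 0.644 with an estimated correlation). Type VI secretion was lower in 12 of 28 and higher in 1 (tssC.1 -2.09; camera adjusted p = 0.0135, adjusted p = 0.315 with an estimated correlation). The deleted formate dehydrogenase genes with a symbol were lower in 4 of 4 (fdnG -2.17, fdxH -1.98; camera adjusted p = 0.0148, adjusted p = 0.402 with an estimated correlation), though the limma adjusted p of fdhF was 0.23 with a pseudocount of 0.1 and 0.102 with quantile normalization. Of the 4 tag-only entries of these loci 2 were lower as well, and PP_RS11325 (-0.23, limma adjusted p = 0.479) and PP_RS11340 (-0.28, limma adjusted p = 0.421) were not called. Purine synthesis was higher in 6 of 11 (purL 0.76, purD 0.74; camera adjusted p = 0.0148, adjusted p = 0.644 with an estimated correlation).

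Several genes outside those lists, or in lists that did not pass, also differed between the treatments. moaB.2 was lower with methanol (-4.38), as were fdhD (-2.91), pfkB (-3.34), ptsP.1 (-3.54), glcE (-3.19), glcF (-3.17) and eat (-3.16). ccoN.1 and ccoO.1 were lower by -3.20 and -2.60 and ccoO.2 was higher by 1.72. The glycine cleavage genes gcvH.1, gcvP.1 and gcvT.1 were lower (-2.48, -2.29 and -2.23), as were bfr.1 (-2.78), metK (-1.82), katG (-1.52) and clpB (-1.06). bamA.2 (2.99), ttgR (0.99) and ahpC (0.93) were higher. Adjusted over the list alone, the counts changed from 5 to 6 lower for the cofactor genes, from 2 to 4 higher for betaine demethylation, from 0 to 2 higher for the Entner-Doudoroff list, from 6 to 2 higher for ribosomal proteins and from 1 to 2 lower for efflux. Of the list genes followed, choW, edd, fdhF, gbcA, hslU, lon.1, pedH, purU.3, rpsN and ttgA lost their call in at least 1 fit with another scaling, pseudocount, filter or set of libraries. With the glucose replicate 1 file as deposited in the shared fit, the count of 2549 was 1382.

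**Figure D4:**
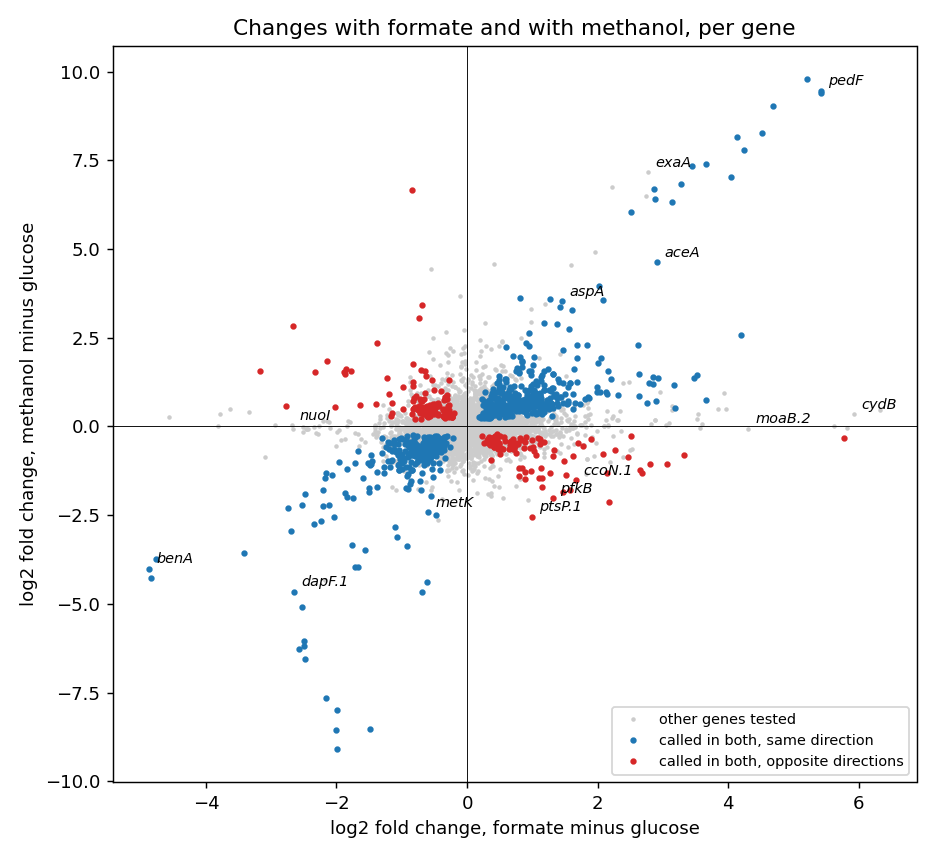
Log2 change with formate (x axis) against log2 change with methanol (y axis), each relative to glucose, for 5219 genes. Blue points passed in both comparisons in the same direction (664 genes), red points passed in both in opposite directions (212 genes) and grey points are all others.

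The responses to formate and to methanol overlapped in part. 385 genes rose and 279 fell with both, among them osmE, phaC.1, hslV and lon.1 upward and benA, dapF.1, metF and ahcY downward. Lists of these sizes would share 190.4 and 129.7 genes if they were independent. In opposite directions 212 genes passed, where independent lists would share 314.8: 100 rose with formate and fell with methanol (such as ptsP.1, pfkB and ccoN.1) and 112 did the reverse. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.405 and a covariance of 0.267. Both comparisons use the same glucose libraries, and 100 simulations of unchanged groups against shared controls gave a mean r of 0.60 and a mean covariance of 0.0337, the observed covariance being larger by 0.234. Splitting the 2 control libraries would leave 1 per comparison and was not done, so part of the excess may come from them.

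Genes that changed together also lay together in the files' order, as bacterial genes are often transcribed in operons. With formate 31 runs of at least 4 neighbouring genes moved in the same direction and held 203 genes, with methanol 25 runs held 159, in the mutant against EM42 2 runs held 8, in the mutant with formate against glucose 29 runs held 185, and between methanol and formate 51 runs held 321. Among 1000 shuffles of the gene order the largest numbers were 47 with formate, 17 with methanol, 33 in the mutant with formate against glucose and 54 between methanol and formate (permutation p = 0.000999 for each, the smallest that 1000 shuffles can give). With formate the longest run was 18 genes with solA and dapF.1 (lower, median log2 change -2.003), followed by 15 higher entries without symbols (1.89) and 14 lower genes that hold complex I (-2.302). With methanol the longest were 23 higher genes with exaA, pedF, pedH and pqqD.2 (6.83) and the 18 with solA and dapF.1 (lower, -5.58), which also fell with formate. The run of 8 with benA, benB and catA.1 was lower with formate (-3.08) and with methanol (-2.93). In the mutant against EM42 the 2 runs were the deleted loci (-5.36 and -3.98), whose genes are neighbours by the deletions themselves, so no shuffle is given for it. Between methanol and formate the longest were 24 higher genes around exaA (3.65) and 17 lower genes with solA and dapF.1 (-3.70).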

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

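The tests of pattern and explanation given here were chosen after the results were seen.

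Formate and methanol moved 212 genes in opposite directions, each passing against glucose in both treatments (limma, Benjamini-Hochberg adjusted p under 0.05). They were chosen for opposite changes against the same glucose libraries, so the direct test of methanol against formate adds no support and gives only sizes. That test gave -3.197 on the log2 scale for ccoN.1, a cbb3-type oxidase subunit that rose with formate and fell with methanol. It gave -3.338 for pfkB and -3.537 for ptsP.1, which rose with formate by 1.31 and 0.99. Both lie in the same run of genes lower with methanol than on glucose, and in no run with formate. It gave -2.476 for gcvH.1 of the glycine cleavage system.

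Formate replicate 2 lists 61 entries that no other library lists, at a median of 0.23 and at most 3.07 FPKM, and among them are genes of the flagellar cluster that EM42 lacks. Whether greater depth is the cause could not be decided. The commonest log2 ratio of its low values to those of glucose replicate 3 is -0.01, over 49 entries. FPKM is already relative to all mapped fragments, so only values that stand for equal read numbers would shift with depth. The smallest value listed is 0.03 here, 0.07 in glucose replicate 3, and 0.01, 0.01 and 0.04 in the mutant libraries. Of 24 flagellar symbols, taken by name and without those above 0 in nearly all libraries, it lists 22. Glucose replicate 1 lists 8, glucose replicate 3 lists 6, glucose replicate 2 lists 1 and the other 8 libraries none. Leaving out widely listed symbols used these same values and lowers the numbers of the other libraries. Traces of RNA from a strain that still carries the cluster are a candidate explanation, found and tested on the same data. No biological explanation was tested.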

How the results depend on the processing

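The alternatives with glucose replicate 1, as deposited or restored, were chosen after seeing the data; all others were planned. Of 6622 values of named genes under the alternatives, 6129 kept their direction and their side of the threshold, 424 lost the call, 22 gained it and 47 reversed. These totals count the fit without glucose replicate 2 under both of its names, the other being the glucose library that shares the formate libraries' record tag. Most named genes called in the mutant against EM42 lie in the deleted loci, and none of the 33 lower entries called outside them was followed. Of the named genes called, 65 of 86 with formate, 46 of 72 with methanol, 7 of 8 in the mutant against EM42, 62 of 83 in the mutant with formate against glucose and 73 of 83 between methanol and formate were called under every alternative other than glucose replicate 1 as deposited. Leaving out glucose replicate 2 or 3 ended 57 and 52 of these calls over all comparisons, 1 control then standing alone and being assumed to vary like the other groups. Read numbers are not given in the sources used here, so what depth limits could only be judged from low values.

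With glucose replicate 1 as deposited, which adds a library of mixed values to the shared spread, the calls numbered 1318 (formate), 849 (methanol), 14 (mutant against EM42), 1267 (mutant with formate against glucose) and 1382 (methanol against formate); restored, 2524, 1916, 62, 2469 and 2586. As deposited these reversed in formate: atpB -1.016, betA -0.609, betB -0.731, bfr.2 -0.475, ccoO.2 -0.22, cyoC -0.865, edd -0.986, fdnG -0.471, fur -1.013, gcvP.2 -0.793 and purT -1.062. In methanol these did: fghA -0.9, hslU -0.512, hslV -0.47, moaA -0.533, purT -0.889, ttgR -0.541 and zwf.1 -1.14. In the mutant with formate against glucose these did: atpB -0.846, betA -0.614, betB -0.673, ccoP.1 -0.039, cyoC -0.92, edd -0.985, fur -0.846 and purT -0.974. Quantile normalization turned atpD to 0.018 and ugpC to 0.038 in methanol, restored glucose libraries with a shared record tag turned coxB to -0.018, and robust limma with weights turned phaC.2 to 0.006 in the mutant against EM42; none of these 4 passed the test in the comparison reported or under that alternative, and the cause was not tested.

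The mutant against EM42 gave 28 calls when only the 2 groups were fitted, with fewer libraries behind the spread, and 166 with robust limma and weights, for which the cause was not tested. Keeping only the glucose library that shares the formate libraries' record tag is the same fit as leaving out glucose replicate 2. Leaving out each library gave 856 to 1375 calls for methanol and 26 to 50 for the mutant against EM42. Values that reversed in that way ranged, for the mutant against EM42, from -1.228 to 0.488 (aceA), -0.022 to 0.425 (atpE), -0.074 to 0.505 (ccoO.1), -0.616 to 0.049 (choW), -1.962 to 0.411 (exaA), -0.479 to 0.245 (fdhA), -0.378 to 0.161 (katG), -0.251 to 0.122 (phaC.2) and -0.469 to 0.239 (ugpC), none of them called. coxB ranged from -0.021 to 0.344 in methanol and fdhA from -0.572 to 0.116 in the mutant with formate against glucose.

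With an estimated correlation 0, 0, 1, 0 and 0 lists passed the set test, in the order above, against 11, 4, 5, 11 and 7. The list that passed for the mutant against EM42 is that of the deleted genes, whose loss is the deletion itself. With no minimum change, runs held 515 genes in formate, 344 in methanol, 537 in the mutant with formate against glucose and 862 between methanol and formate. The correlation of the formate and methanol changes was 0.40 with glucose replicate 1 restored.

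Replicate numbers do not pair the libraries: of 15 pairs with the same number 1 correlated over 0.1 (r from -0.507 to 0.157), and 2 of 11 libraries correlated best with their own number. With the replicate number as a block, 1838, 1327, 33, 1834 and 2399 genes were called and the same lists passed.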

Other observations

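The genes and tests in this part were chosen after values were seen, except the other splits of the libraries at its end, which were planned.

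A run of 8 genes with leuC, leuD, leuB and asd.1 rose with formate (median log2 change 1.30) and was lower with methanol than with formate (-1.59), but was no run between methanol and glucose. leuC stood at 3255, 2883 and 1693 in the formate libraries, at 771 and 852 on glucose and at 556, 563 and 593 with methanol. Cytochrome c maturation genes (ccmI, ccmE and ccmD) lay in a run of 8 that rose with methanol (1.13). The run of 6 with arcC, arcA and both arcD entries, of arginine fermentation, was lower with methanol than with formate (-1.45), and so was the run of 6 with glcC, glcD, glcE and glcF, of glycolate oxidation (-2.22). Tricarboxylic acid cycle genes from sucD to sdhC formed a run of 9 that was higher with methanol than with formate (1.43).

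In glucose replicate 1, 3866 of 5181 compared values lie far below those of the other glucose libraries. A failed or shallow library is argued against, since 25.381% of the values lie at the level of the others. Reading decimals as hours and minutes, as a spreadsheet may do with a value whose decimals are under 60, would leave values with larger decimals intact. Of the 1314 values of at least 24 at the level of the other libraries 0.304% have decimals under 60. The shares are 60.9% and 59.3% in replicates 2 and 3. This check covers values of at least 24 alone. Under 24 only 1 value lay at the level of the other libraries, which this rule by itself does not explain. Of the 3866 values far below, 2005 stand at 24 or more in the other libraries. With the values converted back, the SD of its log2 difference from the geometric mean of replicates 2 and 3 went from 1.73 to 0.291, though the conversion uses their levels. The SD between replicates 2 and 3 was 0.268. That is a difference of 2 single libraries, and a difference from a mean of 2 tends to be smaller, so 0.291 and 0.268 are unlike measures. No biological explanation was tested.

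The libraries with formate differed from each other along an axis that both strains share. Among EM42, exaA stood at 220, 572 and 2785 and in the mutant at 2147, 79.1 and 411, with pedF, pedH, pqqC, aceA and acs.1 in the same order and leuC and gltP in the opposite one. Counting noise is argued against: across 1809 genes with a mean of at least 100, the difference between the extreme libraries of EM42 correlated with that of the mutant at r = 0.895 (0.609 over all genes tested). Material from methanol cultures as the whole cause is argued against by 4 of 29 abundant methanol transcripts, which lie far under the share of the methanol level seen for exaA (17.4% in EM42 and 13.9% in the mutant), the most abundant being at 10220 with methanol but at 55.2 and 54.5 in the EM42 libraries with most and least exaA; exchanged strains are argued against by the deleted genes, at most 0.328 in any mutant library. What sets the axis stays open, and no biological explanation was tested.

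Over the 10 splits of the 6 libraries of methanol and formate the real split called 2549 genes and the highest other 0. Over the 10 splits of the mutant and EM42 libraries with formate the real split called 43 and the highest other 1. Every other split holds libraries of both groups on each side, so genes that differ between the groups widen the spread they are tested against. Few calls in those splits were therefore likely in advance. With 1 split out of 10 as large in each case, the splits are also too few for a share under 0.05.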
